A study of Homo sapiens with 12 samples.

How the data were processed

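Small RNAs were sequenced from HCT116 cells, a human colorectal carcinoma line, in which DROSHA had been knocked out. Per the labels' protocols, 4.5 µg of the plasmid pXC-NLS-DG4 was transfected together with a pCK plasmid, and the amount of the DROSHA-coding pCK plasmid was 4.5 µg. The pCK plasmid was empty or coded for wild-type DROSHA, for the mutant m4 or for a mutant with the belt deleted. What is altered in m4 and what the DG4 plasmid codes for is not stated in the labels. Each of the 4 groups has 3 libraries, 12 in all. The labels number the repeats but do not say whether they are separate cultures, so p-values that compare libraries measure the spread between these samples. The p-values for GC content, folding energy, arm agreement and 3p against 5p arms come from permutations over hairpins or miRNAs instead. Per the labels' protocols, total RNA was extracted with TRIzol, RNA of 19 to 24 nt was taken from 10 µg of total RNA on a 15% gel, and libraries were made with a NEBNext small RNA kit.

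The deposited table gives raw read counts per mature miRNA and hairpin, with no normalisation by the authors that the values show: all entries are whole numbers of at least 1, and column totals differ. Per the submitters' processing notes, cutadapt, Bowtie2 and the genome build hg38 were used, without versions or settings. The counter, the miRNA annotation, the treatment of reads that fit several hairpins and the use of strand are not stated. The table has 1409 lines for 978 hairpins and 1286 mature names, 712 on the 5p arm and 697 on the 3p arm. Of its 16908 cells 7220 are blank (42.7%), and none is 0, so blanks were read as 0. Table totals ranged from 132667 to 407461 reads per library.

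Many reads stand in the table more than once. Of 84 mature names listed under several hairpins, 36 had more than 120 reads in total, and 28 of these 36 had the same reads in every line. Reads were called the same when they differed by at most 5 reads or 5% in each library. Lines of 1 mature name were therefore collapsed to the line with the most reads, and 9 pairs of names with the same reads were merged. The pairs are miR-103a-3p with miR-103b, miR-122-5p with miR-122b-3p, miR-24-3p with miR-3074-5p, miR-423-5p with miR-3184-3p, miR-423-3p with miR-3184-5p, miR-7-5p with miR-3529-3p, and both arms of miR-3158, miR-3913 and miR-625. A tolerance of 3 reads or 2% over at least 240 reads was used first and gave 6 pairs; it was loosened after the first results had been seen. After collapsing, 1277 mature miRNAs of 892 hairpins were left, with 101886 to 332081 reads per library. This step was not part of the plan made before the data were examined, so both the earlier tolerance and the sum over hairpin copies without merging were run as alternatives chosen after seeing the data. Near-identical sequences whose reads the counting could have divided stay uncertain: miR-320a, b and c, miR-378a, c and d, miR-103a and miR-107, the miR-30 family, and miR-203a-3p with miR-203b-5p, which lie on opposite strands of 1 locus.

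The choice of scaling, tests, lists and naming rule was made before the data were examined. Because DROSHA acts on most miRNA hairpins at once, library sizes were taken from hairpins that mature without DROSHA: miR-320 (a to e, summed), miR-484, and the mirtrons and mirtron-like hairpins miR-877, miR-1224, miR-1225, miR-1226, miR-1227, miR-1228, miR-1229 and miR-1236. The size factor was the median ratio to the geometric mean over the 5 of these features with at least 20 reads in every library (miR-320, miR-484, miR-877, miR-1224 and miR-1226). In simulations with known answers this scaling left the median of unchanged miRNAs off 0 by -0.19 to 0.14 on the log2 scale. The simulated changes spared the reference list, so they could not test whether it stays constant. In the data the 5 features differed among themselves. For belt deletion against wild type their log2 changes ran from -0.37 (miR-484) to 0.76 (miR-1224). For m4 against empty they ran from -0.54 (miR-320) to 0.42 (miR-1226). Scaled reads below are counts divided by the size factor.

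Differences between groups were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, R 4.3.3), in 1 fit of all 12 libraries without covariates. The filterByExpr filter kept 310 miRNAs, p-values were adjusted by the Benjamini-Hochberg method over them, and a call means an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of F. Adjusted p-values in the text come from this edgeR test unless another tool is named. The naming rule took, for wild type against empty and for each mutant against wild type, the 6 largest rises and 6 largest falls among called miRNAs with a mean of at least 100 reads in the higher group and no overlap between groups, the 10 miRNAs with the highest level with wild type, and the 5 most abundant members of the DROSHA-independent list. For the other contrasts it took the 3 largest rises and falls. The rule found fewer falls or rises than it asked for in several contrasts.

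A ratio per library divided the reads of all miRNAs outside the DROSHA-independent and the snoRNA- or tRNA-derived lists by the reads of the DROSHA-independent list. Its log2 was compared by a two-sided exact permutation test, which with 3 against 3 cannot go below p = 0.1. The share of reads on the 5p and 3p arms was tested in edgeR with 2 columns per library and the library as a factor, for 47 of 407 candidate hairpins with at least 10 reads on each arm in total and at least 20 reads in each library. In 10 of the 47 the reads of an arm stand under another hairpin as well, so the ratio may mix hairpins; leaving these 10 out was an alternative chosen after seeing the data. The 4 contrasts tested for arms were wild type against empty, each mutant against wild type, and belt deletion against m4.

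There were 19 lists: DROSHA-independent, snoRNA- or tRNA-derived, miR-17-92 with its paralogous clusters, let-7, miR-200, the miR-183 cluster, miR-15/16, miR-30, miR-29, miR-34, miR-23/27/24, the miR-10 superfamily (miR-10, miR-99, miR-100 and miR-125), intestinal epithelium and colon cancer, miR-221/222, miR-130/301, miR-148/152, miR-181, the cluster of miR-424 and miR-503, and markers of other cell types (liver, muscle, neurons, blood, endothelium, smooth muscle). Each was summarised by its called members, over all miRNAs and adjusted over the list alone. Lists with at least 5 members were tested with camera in limma 3.58.1, at a preset correlation of 0.01 and with an estimated correlation. Of the 54 list and contrast pairs so tested, 33 calls made with the preset correlation were lost with an estimated one.

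Alternatives were TMM, DESeq2 and total-count scaling, scaling by the sum of the reference list or without miR-320, the DESeq2 1.42.0 Wald test, other filters on low counts, a fold threshold, fits of 6 libraries, a replicate block, and leaving out each library in turn. Whether replicate numbers pair the libraries was checked on 155 miRNAs by the correlation of deviations from group means. For m4 and wild type all 3 pairs were above 0.1 (0.129, 0.419 and 0.331), in no other contrast were they, and the labels do not say what a number marks. A fit of these 6 libraries with a replicate block was therefore added after the data were seen. For arms, limma on log2((5p + 1)/(3p + 1)) and a minimum of 100 reads in each of the 12 libraries were run. That minimum left mir-30a, mir-30e, mir-10a, mir-216a, mir-99b and mir-10401 untested, as some libraries hold fewer reads of them. Contrasts that share a group were set against 50 simulated pairs of unchanged groups. Hairpin positions and host genes come from GENCODE 29 on hg38, which matched 868 of 892 hairpins. Folding energies were computed with RNAfold 2.7.2, and other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

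The edgeR steps were tested on simulated counts with 200 changed miRNAs among 310. At a log2 change of 2 the step recovered 94.1% of changed miRNAs for wild type against empty, 91.5% for m4 against empty, 94.4% for belt deletion against empty, 88.9% for m4 against wild type, 83.6% for belt deletion against wild type and 83.1% for belt deletion against m4. At a log2 change of 1 the same 6 values were 30.3%, 18.0%, 35.0%, 26.7%, 26.6% and 25.0%. False calls made up 0.699% to 3.27% of calls. The arm test found, at log2 changes of 2 and 3, 2 of 5 and 4 of 10 changed hairpins for wild type against empty (with 1 false call among 7 calls), 2 of 8 and 4 of 7 for m4 against wild type, 2 of 7 and 7 of 8 for belt deletion against wild type, and 1 of 4 and 6 of 11 for belt deletion against m4 (0 false calls in these 3). Its first simulation model did not match the fitted model and was replaced. A library with no read of a miRNA allows up to 3 reads, which covers counting error only, as reads without molecular identifiers are not independent molecules. DROSHA mRNA is not seen by this assay, and target genes were not analysed here. The amount of DROSHA made in each group is therefore unknown, and an effect of a mutation cannot be told apart from a difference in that amount.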

Results

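Mature miRNAs were counted in 12 small RNA libraries of HCT116 cells that lack DROSHA, the nuclear RNase III enzyme that cuts most primary miRNA transcripts. Cells received an empty plasmid, wild-type DROSHA, the mutant m4 or a mutant without the belt, each in 3 libraries and each together with the plasmid pXC-NLS-DG4. The table held 331083, 269550 and 372985 reads for empty plasmid replicates 1, 2 and 3. The totals were 359390, 217141 and 277903 for wild type, 132667, 298695 and 139200 for m4, and 390428, 286810 and 407461 for the belt deletion. Between 649 and 800 mature miRNAs were detected per library. The most abundant miRNA was miR-320a-3p in every empty and m4 library, in wild type replicate 3 and in belt deletion replicate 3, and miR-21-5p in the other 4 libraries. Levels below are mean scaled reads ± SD (n = 3), changes are log2 values with their standard error (SE), and positions are on hg38. Members of a list named beside its count, outside the naming rule, were chosen after their values were seen.

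The reads of other miRNAs relative to those of DROSHA-independent hairpins, such as miR-320a and mirtrons, which mature without DROSHA, were lowest with the empty plasmid and highest with wild type. The log2 ratio was -2.13 ± 0.22 (SD, n = 3) with the empty plasmid, 0.80 ± 0.62 with wild type, -0.98 ± 0.62 with m4 and 0.53 ± 0.29 with the belt deletion. Relative to the empty plasmid the ratio was 7.67-fold higher with wild type, 2.22-fold higher with m4 and 6.34-fold higher with the belt deletion. It was 3.45-fold lower with m4 than with wild type and 2.86-fold higher with the belt deletion than with m4. In these 5 comparisons the groups did not overlap, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 can give. Belt deletion and wild type overlapped, with a ratio 1.21-fold lower with the belt deletion (exact permutation p = 0.5). With a geometric mean over miRNAs with at least 10 reads in every library, in place of the sum, the log2 differences shrank. They were 1.55, 0.94 and 1.43 against the empty plasmid for wild type, m4 and belt deletion, -0.61 for m4 against wild type and 0.49 for belt deletion against m4. This limit drops miRNAs near 0 without DROSHA, such as miR-34a-5p and miR-503-5p, so part of the shrinkage may follow from it. The sum is weighted toward abundant miRNAs. Without its 3 most abundant, miR-21-5p, let-7i-5p and miR-3615, m4 against wild type went from -1.79 to -1.09. Belt deletion against m4 went from 1.51 to 0.73. Against the empty plasmid the differences were then 2.28, 1.19 and 1.91 for wild type, m4 and belt deletion. Without miR-320 in the reference the m4 libraries stood 0.57 above the empty ones. Belt deletion against wild type ranged from -0.62 without wild type replicate 3 to -0.02 without wild type replicate 2.

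**Figure D1:**
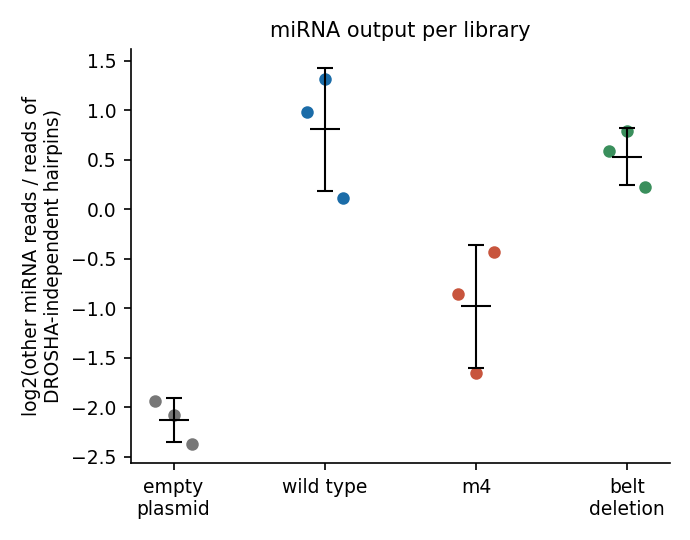
Log2 ratio of the reads of other miRNAs to the reads of DROSHA-independent hairpins (y axis) in each of the 12 libraries (points), with mean and SD per group (bars). The group means are -2.13 for the empty plasmid, 0.80 for wild type, -0.98 for m4 and 0.53 for the belt deletion, and the wild type and belt deletion libraries overlap.

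The comparison of wild type with the empty plasmid asks which mature miRNAs come back when DROSHA is supplied. miR-21-5p, an oncogenic miRNA abundant in colorectal tumours, rose 39.4-fold, from 2052 ± 364 to 80950 ± 29538 scaled reads. let-7i-5p, of the let-7 family that represses LIN28 and RAS, rose 70.1-fold, from 335 ± 70.7 to 23505 ± 6803. miR-10a-5p, encoded in the HOXB cluster, rose 91.2-fold, and miR-30a-5p rose 107-fold, from 15.9 ± 5.52 to 1717 ± 705. The DROSHA-independent miR-320a-3p stood at 81236 ± 12446 with the empty plasmid and 63039 ± 8267 with wild type, without a call (adjusted p = 0.446). The miR-320 family is among the features that set the scaling, which draws its change toward 0.

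Of 310 miRNAs tested, 132 rose and 2 fell with wild type. Positions and tests of miRNAs taken by the naming rule follow. The largest rises among called miRNAs with a mean of at least 100 reads in the higher group and no overlap between groups come first, and less abundant miRNAs can have changed more. miR-30a-5p (MIR30A, chromosome 6, 71403551 to 71403621, an intron of LINC00472) rose by 6.74 (SE 0.42, adjusted p = 5.5e-24). miR-10a-5p (MIR10A, chromosome 17, 48579838 to 48579947) went from 68.1 ± 5.81 to 6219 ± 2201 (6.51, SE 0.41, adjusted p = 9.23e-24). let-7i-5p (MIRLET7I, chromosome 12, 62603686 to 62603769) rose by 6.13 (SE 0.41, adjusted p = 9.42e-23). miR-182-5p and miR-183-5p, of 1 cluster on chromosome 7 that is active in sensory cells and in many carcinomas, rose 49.5-fold and 44.5-fold, to 2080 ± 643 and 1477 ± 347. miR-23a-3p rose 47.3-fold to 183 ± 61.2. miR-21-5p (MIR21, chromosome 17, 59841266 to 59841337, in an exon of VMP1) rose by 5.30 (SE 0.41, adjusted p = 7.69e-20). Among the other abundant miRNAs, miR-7-5p rose 26.0-fold to 8337 ± 2914, miR-151a-3p rose 24.7-fold to 4078 ± 1170 and miR-100-5p rose 12.2-fold to 4124 ± 1262. The largest fall was that of miR-216a-3p (MIR216A, chromosome 2, 55988950 to 55989059), a pancreas-enriched miRNA, from 551 ± 158 to 38.9 ± 15.8 (-3.82, SE 0.61, adjusted p = 8.04e-05). The other fall, chosen for mention after its values were seen, was miR-3614-5p (-1.07, adjusted p = 0.0266). miR-34a-5p, miR-503-5p and miR-129-5p had no read in any empty library and stood at 19.5 ± 6.13, 14.3 ± 1.90 and 6.10 ± 3.13 with wild type. Over the 132 risen miRNAs the median fold was 19.0 (18.8 with these 3 set to the bound of 3 reads over the group). Groups did not overlap for 162 miRNAs, where chance gives 10%.

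Most members rose in most lists of canonical miRNAs. The called members were 10 of 10 of let-7, 7 of 7 of miR-17-92 with its paralogous clusters (a MYC target and oncogenic cluster), 8 of 8 of miR-23/27/24, 7 of 9 of miR-30, 9 of 10 of the miR-10 superfamily (miR-10, miR-99, miR-100 and miR-125) and 7 of 7 of the list for intestinal epithelium and colon cancer. The counts adjusted over the list alone were the same for these lists. Their camera calls with the preset correlation were lost with an estimated one. The values were adjusted p = 0.225 with an estimated correlation for miR-17-92, adjusted p = 0.197 with an estimated correlation for miR-23/27/24 and adjusted p = 0.210 with an estimated correlation for the other 4 lists. All members rose in the smaller lists of the miR-183 cluster (3), miR-221 with miR-222 (4, of which 3 under TMM, DESeq2 and total-count scaling), miR-148 with miR-152 (3) and miR-181 (3). All members also rose in miR-15/16 (2, of which 1 under total-count scaling), miR-29 (2), the cluster of miR-424 and miR-503 (2), miR-34 (1, the p53-induced miR-34a-5p) and miR-130 with miR-301 (1). The counts adjusted over the list alone were the same for these 9 lists. In the miR-200 family, which represses ZEB1 and ZEB2, 2 of 5 members rose (2 adjusted over the list alone), but none under TMM or total-count scaling. Its median was 0.86, while camera pointed down (adjusted p = 0.767). Of the markers of other cell types, miR-126-3p of endothelium (5.37) and miR-9-5p of neurons (1.77) rose (2 of 4, 2 adjusted over the list alone). The liver and smooth muscle markers miR-122-5p and miR-143-3p went from 78.8 to 48.9 and from 133 to 112 without a call, and both were called lower under TMM, DESeq2 and total-count scaling.

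None of the 15 DROSHA-independent miRNAs was called by edgeR (2 at an unadjusted p under 0.05, 2 by DESeq2, 0 adjusted over the list alone), whereas 11 fell under TMM, 9 under DESeq2 and 10 under total-count scaling and 1 rose with the sum of the reference. Their median was -0.35. Their camera call downward was lost (adjusted p = 0.197 with an estimated correlation). The size factors come from members of this list, which draws its changes toward 0 here and in the other contrasts. Its lack of calls is therefore largely set by the scaling and is no separate result. The named members had values of -0.37 (miR-320a-3p, adjusted p = 0.446), -0.41 (miR-320b, adjusted p = 0.375), -0.69 (miR-320c, adjusted p = 0.0705), -0.35 (miR-1224-5p, adjusted p = 0.417) and -0.06 (miR-877-5p, adjusted p = 0.923). miR-3615 (-0.51, adjusted p = 0.207) and miR-7706 (-0.57, adjusted p = 0.163), among the 10 most abundant miRNAs with wild type, were not called either and fell under those 3 scalings. None of the 6 miRNAs on the snoRNA- or tRNA-derived list was called by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2, 0 adjusted over the list alone), and 1 fell under TMM, DESeq2 and total-count scaling. The median of this list was 0.51 against a camera direction of down (adjusted p = 0.195). Scaling set the balance of calls. Under TMM 218 miRNAs were called, of which 93 fell. The rises and falls were 126 and 68 under DESeq2 size factors, 123 and 71 under total counts, and 137 and 1 with the sum of the reference. The median of all miRNAs moved by -0.86, -0.66 and -0.82 under TMM, DESeq2 size factors and total counts. The sum of the reference moved it by 0.39.

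The ratio of 5p to 3p reads was called changed for 8 of 47 hairpins between wild type and the empty plasmid. For 3 of the 8, mir-92a-2, mir-16-2 and mir-423, reads stand under another hairpin as well (miR-92a-3p, miR-16-5p and both arms of mir-423), so their ratio need not be the share of 1 hairpin. Without the 10 hairpins with such reads, a test added after the result was seen, 3 of 37 were called, mir-30a, mir-222 and mir-216a. The 3p share of mir-30a was lower with wild type, 10.1% ± 4.21 against 37.6% ± 2.50 (SD, n = 3), a log2 change of the 5p to 3p ratio of 2.50 (adjusted p = 0.00037). The share of mir-222 was 98.6% ± 0.508 against 88.1% ± 3.88, and that of mir-216a was 79.6% ± 14.7 against 98.3% ± 0.229. The 3p shares of mir-99b (24.5% against 7.51%) and mir-1307 (98.97% against 92.7%) were called as well, but both calls ended without some library and in the test without the 10 hairpins (adjusted p = 0.0565 and 0.0643). Without the library in question, the adjusted p for mir-99b was 0.0640 (wild type 2), 0.125 (wild type 3), 0.0987 (empty 1), 0.0942 (empty 2) and 0.251 (empty 3), and for mir-1307 it was 0.0632, 0.0581 and 0.0568 (wild type 1, 2 and 3), 0.0941 (empty 1) and 0.465 (empty 3). With at least 100 reads per library, 16 hairpins were tested and 1 (mir-222) was called; mir-30a and mir-216a were not among those tested.

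The m4 mutant against the empty plasmid asks whether m4 restores any miRNA. miR-27a-5p, from the cluster of miR-23a, miR-27a and miR-24-2, rose 18.4-fold with m4, from 39.8 ± 16.3 to 736 ± 205 (4.20, SE 0.37, adjusted p = 1.73e-15). miR-126-3p, encoded in an intron of EGFL7, rose 15.7-fold to 150 ± 33.6 (3.97, SE 0.38, adjusted p = 5.45e-14), and miR-10a-5p rose 11.97-fold to 817 ± 220 (3.58, SE 0.36, adjusted p = 2.04e-13). miR-216a-3p fell to 77.9 ± 37.6 (-2.83, SE 0.57, adjusted p = 0.00112).

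In all, 127 miRNAs rose and 3 fell with m4 against the empty plasmid (84 and 19 under TMM scaling, 144 and 3 under total counts, 168 and 1 with the sum of the reference). The other falls were miR-6747-3p (-1.53, adjusted p = 0.00126) and miR-6808-3p (-1.69, adjusted p = 0.00775), chosen for mention after their values were seen. The risen members were 8 of 10 of let-7, 7 of 7 of miR-17-92 (6 under TMM), 9 of 10 of the miR-10 superfamily (7 under TMM) and 7 of 7 of the intestinal list (6 under TMM), with the same counts adjusted over the list alone. Camera calls for let-7, miR-17-92 and the miR-10 superfamily were lost (adjusted p = 0.338 with an estimated correlation for each), as was that for the intestinal list (adjusted p = 0.308 with an estimated correlation). In miR-23/27/24, 8 of 8 rose (7 under TMM; 8 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation), and in miR-30 it was 7 of 9 (5 under TMM; 7 adjusted over the list alone; camera adjusted p = 0.186). All 5 miR-200 members rose (5 adjusted over the list alone; camera adjusted p = 0.345), but 1 under TMM. All members of miR-183 (3), miR-15/16 (2, but 0 under TMM), miR-29 (2, but 1 under TMM), miR-130 with miR-301 (1, but 0 under TMM) and miR-148 with miR-152 (3, but 2 under TMM) rose, as did 3 of 4 of miR-221 with miR-222 (2 under TMM), 2 of 3 of miR-181 and 2 of 4 markers of other cell types (2, with 1 lower, under TMM), with the same counts adjusted over the list alone. edgeR called 0 of 1 of miR-34 (0 at an unadjusted p under 0.05, 0 by DESeq2) and 0 of 2 of the cluster of miR-424 and miR-503 (1 at an unadjusted p under 0.05, 0 by DESeq2), with 0 adjusted over the list alone for both. Of the DROSHA-independent list, miR-320d (2.15, adjusted p = 0.0242) and miR-1229-3p (1.16, adjusted p = 0.0218) rose (2 of 15, 0 adjusted over the list alone), whereas 5 fell under TMM, and the list's median of -0.10 and mean of 0.10 differ in sign. Its camera call downward was lost (adjusted p = 0.132 with an estimated correlation). Of the snoRNA- or tRNA-derived list 1 of 6 rose, miR-1260b (1.63, adjusted p = 0.0338; 0 adjusted over the list alone, 0 under TMM). Against the main scaling the median miRNA moved by -0.65 under TMM, -0.47 under DESeq2 size factors, 0.25 under total counts and 0.60 with the sum of the reference.

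The belt deletion against the empty plasmid asks the same of the other mutant. miR-30a-3p rose 80.1-fold, from 9.36 ± 2.14 to 759 ± 151 (6.32, SE 0.42, adjusted p = 1.07e-22). miR-10a-5p rose 79.6-fold to 5430 ± 1162 (6.32, SE 0.41, adjusted p = 6.64e-23), and miR-27b-3p rose 77.3-fold, from 42.1 ± 11.02 to 3259 ± 708 (6.27, SE 0.41, adjusted p = 6.64e-23). The markers of other cell types miR-126-3p and miR-9-5p rose here as with wild type (2 of 4, 2 adjusted over the list alone; 1 marker lower under TMM).

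In all, 133 miRNAs rose and 1 fell, the fall being miR-6808-3p (-1.37, adjusted p = 0.0227), chosen for mention after its value was seen. The split was 114 and 42 under TMM, 115 and 34 under DESeq2 size factors, 109 and 33 under total counts, and 136 and 0 with the sum of the reference, as the median miRNA moved by -0.75, -0.65 and -0.77, and by 0.24 with the sum of the reference. The risen members were 10 of 10 of let-7 (9 under TMM; adjusted p = 0.251 with an estimated correlation), 7 of 7 of miR-17-92 (6 under total counts; adjusted p = 0.345 with an estimated correlation) and 7 of 7 of the intestinal list (adjusted p = 0.251 with an estimated correlation). They were 8 of 8 of miR-23/27/24 (adjusted p = 0.150 with an estimated correlation) and 7 of 9 of miR-30 (adjusted p = 0.275 with an estimated correlation). The counts adjusted over the list alone were the same for these 5 lists. In the miR-10 superfamily it was 8 of 10 (7 under TMM; 9 adjusted over the list alone; adjusted p = 0.310 with an estimated correlation). All members rose in miR-183 (3), miR-15/16 (2, but 1 under TMM), miR-29 (2, but 0 under TMM), miR-34 (1, but 0 under TMM), miR-221 with miR-222 (4, but 3 under TMM), miR-130 with miR-301 (1), miR-148 with miR-152 (3) and the cluster of miR-424 and miR-503 (2), and 2 of 3 in miR-181, with the same counts adjusted over the list alone. In the miR-200 family 3 of 5 rose (3 adjusted over the list alone), but 0 under TMM, with a median of 0.97 against a camera direction of down (adjusted p = 0.724). Of the DROSHA-independent list 1 of 15 rose, miR-320d (2.39, adjusted p = 0.0133; 0 adjusted over the list alone), whereas 6 fell under TMM and total-count scaling, and the list's median of -0.01 and mean of 0.03 differ in sign. Its camera call downward was lost (adjusted p = 0.150 with an estimated correlation). Of the snoRNA- or tRNA-derived list 1 of 6 rose, miR-1260b (1.80, adjusted p = 0.0140; 1 adjusted over the list alone), and 1 fell under TMM.

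The m4 mutant against wild type asks how much DROSHA output m4 lacks. miR-21-5p reached 7446 ± 1928 scaled reads with m4, 10.9-fold below wild type, and let-7i-5p reached 1170 ± 355, 20.1-fold below. miR-30a-5p fell 22.0-fold, to 78.2 ± 22.1, and miR-221-3p, which represses the cell cycle inhibitor CDKN1B, fell 14.6-fold, from 2638 ± 809 to 181 ± 60.6. Of the 132 miRNAs that rose with wild type, 105 were lower with m4 and 27 were not called. The m4 mutant restored a median of 20.5% of the gain seen with wild type (quartiles 10.4% and 37.0%; 20.5% with the 3 miRNAs absent from empty libraries at their bound), a median level 3.93-fold below wild type. These counts and shares, like those of the belt deletion below, come from the main scaling only. Under total counts 133 miRNAs rose and 60 fell with m4 against wild type.

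In all, 106 miRNAs fell and 11 rose with m4 against wild type. The largest falls among called miRNAs with a mean of at least 100 reads in the higher group and no overlap between groups were those of miR-30a-5p (-4.46, SE 0.37, adjusted p = 7.49e-17), let-7i-5p (-4.33, SE 0.37, adjusted p = 1.88e-16), and miR-221-3p (-3.87, SE 0.36, adjusted p = 3.92e-15). The next were miR-30e-5p (from 290 ± 109 to 22.0 ± 8.37; -3.72, SE 0.41, adjusted p = 2.77e-12), miR-378c (from 1162 ± 393 to 90.5 ± 21.8; -3.68, SE 0.35, adjusted p = 1.33e-14) and miR-221-5p (from 251 ± 84.7 to 21.3 ± 15.4; -3.57, SE 0.43, adjusted p = 2.33e-10; -4.22 without m4 replicate 3). Among the most abundant, miR-21-5p fell by 3.44 (SE 0.37, adjusted p = 1.89e-12), miR-151a-3p by 3.45 to 373 ± 111, miR-10a-5p by 2.93, miR-7-5p by 2.79 to 1208 ± 333 and miR-100-5p by 1.69 to 1278 ± 444 (adjusted p = 2.03e-05). The rise past the naming rule was miR-3182 (MIR3182, chromosome 16, 83508346 to 83508408, an intron of CDH13), from 161 ± 58.8 to 408 ± 134 (1.35, SE 0.37, adjusted p = 0.00202). miR-3615 (0.20, adjusted p = 0.663), miR-7706 (0.25, adjusted p = 0.596), miR-320a-3p (-0.08, adjusted p = 0.863), miR-320b (-0.06, adjusted p = 0.903), miR-320c (0.05, adjusted p = 0.906) and miR-877-5p (0.01, adjusted p = 0.973) were not called. However, miR-320a-3p and miR-320b were called higher with m4 under total-count scaling (0.82 and 0.84). miR-1224-5p (0.69, adjusted p = 0.0771) was called without m4 replicate 1 (adjusted p = 0.0121, range over the alternatives 9.15e-06 to 0.426).

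Most members fell in 6 of the larger lists, but none of these falls was called by camera with an estimated correlation, and total counts left fewer. They were 7 of 7 of miR-17-92 (2 under total-count scaling; adjusted p = 0.273 with an estimated correlation), 8 of 10 of let-7 (6 under total counts; adjusted p = 0.259 with an estimated correlation), 8 of 9 of miR-30 (4 under total counts; adjusted p = 0.259 with an estimated correlation) and 6 of 7 of the intestinal list (3 under total counts; adjusted p = 0.259 with an estimated correlation). In miR-23/27/24 it was 7 of 8 (4, with 1 higher, under total counts; adjusted p = 0.259 with an estimated correlation). The counts adjusted over the list alone were the same for these 5 lists. In the miR-10 superfamily it was 7 of 10 (8 adjusted over the list alone; 6, with 1 higher, under total counts; adjusted p = 0.266 with an estimated correlation). All members of miR-183 (3, but 2 under total counts), miR-130 with miR-301 (1, but 0 under total counts), miR-148 with miR-152 (3, but 1 under total counts) and miR-34 (1) fell, as did 1 of 2 of miR-15/16, 1 of 2 of miR-29 (0 under total counts), 2 of 3 of miR-181 (1 under total counts) and 1 of 4 markers of other cell types (miR-126-3p; 3 higher under total counts), with the same counts adjusted over the list alone. For miR-221 with miR-222 it was 3 of 4 (4 adjusted over the list alone; 2 under total counts), and for the cluster of miR-424 and miR-503 it was 1 of 2 (2 adjusted over the list alone). The other cell type markers had a median of 0.24 against a mean of -0.07. edgeR called 0 of 5 of miR-200 (0 at an unadjusted p under 0.05, 0 by DESeq2), 0 of 15 DROSHA-independent miRNAs (1 at an unadjusted p under 0.05, 1 by DESeq2) and 0 of 6 on the snoRNA- or tRNA-derived list (0 at an unadjusted p under 0.05, 0 by DESeq2), and 0 adjusted over the list alone. Of these, 4, 11 and 4 were called higher under total counts. The camera call upward for the DROSHA-independent list was lost (adjusted p = 0.259 with an estimated correlation).

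The split of 11 rises and 106 falls became 43 and 97 under TMM, 39 and 97 under DESeq2 size factors, 133 and 60 under total counts, and 6 and 87 with the sum of the reference, as the median miRNA moved by 0.21, 0.19, 1.05 and 0.17. Of the 132 miRNAs, 109 stood above the empty plasmid in both mutant m4 and wild type, where independent calls would share 54.1 and simulated unchanged groups 0.02. The 105 that rose with wild type and were lower with m4 compare with 45.1 and 0.02. Each pair of contrasts shares 3 libraries, and part of the excess may come from them. Unchanged groups give hardly any calls, so their shared counts were bound to be near 0. They cannot show how much the shared libraries add among real calls.

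**Figure D2:**
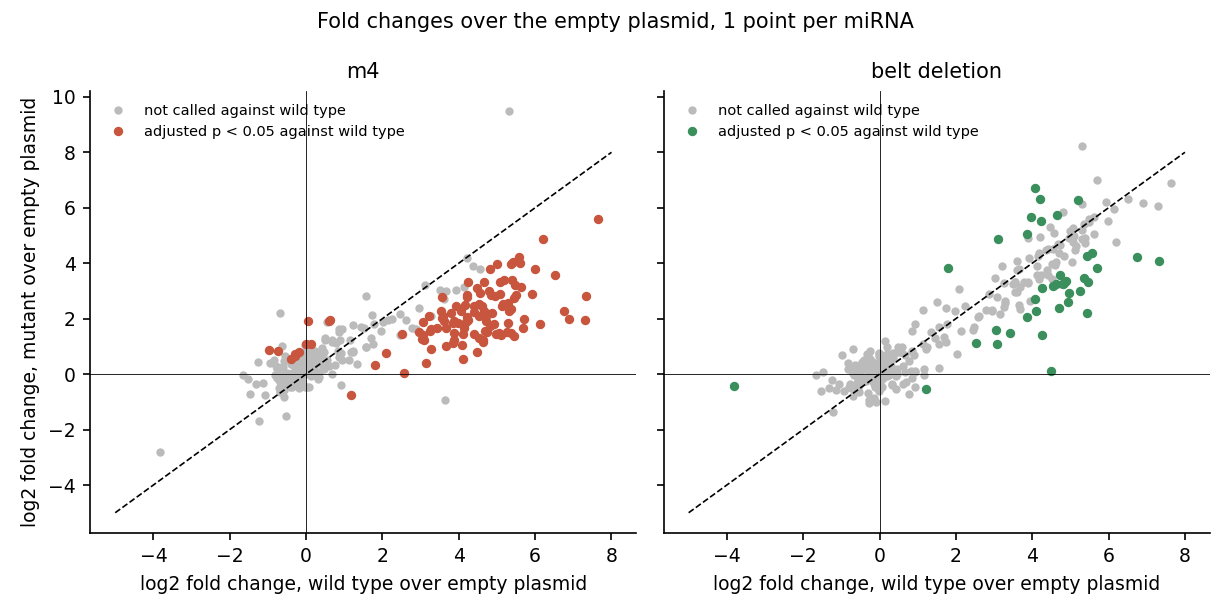
Log2 fold change over the empty plasmid with wild type (x axis) and with m4 or the belt deletion (y axis, 1 panel each) for the 310 miRNAs tested (points), coloured where the mutant differed from wild type at an adjusted p under 0.05; the dashed line marks equality. With m4 106 coloured points lie below wild type and 11 above, and with the belt deletion 29 lie below and 10 above; under total-count scaling m4 has 133 above and 60 below.

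The 3p share of mir-30a was higher with m4 than with wild type, 45.3% ± 7.15 against 10.1% ± 4.21 (log2 change of the 5p to 3p ratio -2.98, adjusted p = 4.7e-07). It was called with each library left out. That of mir-99b was lower, 6.32% ± 2.38 against 24.5% ± 5.56 (2.15, adjusted p = 0.0075), but not called without wild type replicate 3 (adjusted p = 0.0823). The other of the 3 calls among 47 hairpins was mir-16-2 (adjusted p = 0.0306), whose 5p reads stand under mir-16-1 as well, so that it gives no share of 1 hairpin. It was not called without wild type 1 (0.196), wild type 3 (0.0823), m4 1 (0.189) or m4 2 (0.0723), or by limma (0.162 without and 0.182 with a replicate block). Without hairpins that have such reads 2 of 37 were called. With at least 100 reads per library edgeR called 0 of 16 (2 at an unadjusted p under 0.05, 0 by limma), but mir-30a and mir-99b were not among the 16.

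The belt deletion against wild type asks the same of the belt mutant. miR-21-5p, at 74877 ± 6226, and let-7i-5p, at 20736 ± 2349, were not called different from wild type (adjusted p = 0.858 and 0.764), while both arms of mir-30a and of mir-30e changed in opposite directions. miR-30a-5p fell 5.71-fold to 300 ± 47.8 and miR-30a-3p rose 4.34-fold from 175 ± 44.9 to 759 ± 151. miR-30e-5p fell 4.78-fold to 60.6 ± 12.9 and miR-30e-3p rose 2.29-fold from 196 ± 104 to 450 ± 48.9. Of the 132 miRNAs that rose with wild type, 29 were lower with the belt deletion, 9 were higher and 94 were not called, with a median of 66.4% of the wild-type gain restored (quartiles 42.8% and 107%; 66.4% with the 3 miRNAs absent from empty libraries at their bound).

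In all, 10 miRNAs rose and 29 fell with the belt deletion against wild type (26 and 29 under TMM, 17 and 32 under DESeq2 size factors, 12 and 25 under total counts, 5 and 24 with the sum of the reference). The largest rises among called miRNAs with a mean of at least 100 reads in the higher group and no overlap between groups were miR-216a-3p (to 414 ± 269; 3.41, SE 0.60, adjusted p = 0.00104), miR-30a-3p (2.12, SE 0.34, adjusted p = 1.05e-06), and miR-769-5p (from 68.2 ± 23.3 to 221 ± 82.2; 1.70, SE 0.38, adjusted p = 0.000375). The next were miR-27a-5p (from 745 ± 162 to 1839 ± 408; 1.30, SE 0.33, adjusted p = 0.0018), miR-30e-3p (1.19, SE 0.36, adjusted p = 0.0133) and miR-28-3p (from 171 ± 59.5 to 364 ± 145; 1.10, SE 0.38, adjusted p = 0.0437). miR-28-3p was not called without wild type 1 (0.121), wild type 3 (0.210), belt deletion 2 (0.312) or belt deletion 3 (0.0753), by DESeq2 (0.0512), without a filter (0.0579) or with hairpin copies summed (0.0601). miR-30e-3p was not called without wild type 2 (0.0821), wild type 3 (0.144), belt deletion 1 (0.0524) or belt deletion 2 (0.0513). Both, and miR-27a-5p, also missed the threshold with the sum of the reference (adjusted p = 0.353, 0.205 and 0.0976). The largest falls within the same limits were those of miR-30a-5p (-2.51, SE 0.34, adjusted p = 1.79e-08), miR-30d-5p (from 1478 ± 311 to 295 ± 107; -2.33, SE 0.34, adjusted p = 1.13e-07), and miR-7-5p (to 1686 ± 188; -2.31, SE 0.34, adjusted p = 1.23e-07). The next were miR-30e-5p (-2.26, SE 0.38, adjusted p = 2.59e-06), miR-22-3p (from 221 ± 58.0 to 50.5 ± 5.04; -2.13, SE 0.37, adjusted p = 6.48e-06) and let-7g-5p (from 1694 ± 356 to 417 ± 60.9; -2.02, SE 0.33, adjusted p = 1.05e-06). miR-151a-3p fell by 1.37 to 1579 ± 622 (adjusted p = 0.00118). miR-10a-5p (-0.20), miR-100-5p (0.14), miR-3615 (0.16), miR-7706 (0.81), miR-320a-3p (0.13), miR-320b (0.15), miR-320c (0.72), miR-1224-5p (0.78) and miR-877-5p (0.04) were not called, with adjusted p from 0.0964 to 0.950. Under TMM, miR-7706, miR-320c and miR-1224-5p were called higher.

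In miR-17-92, 4 of 7 members fell (5 adjusted over the list alone; 2 with the sum of the reference; adjusted p = 0.790 with an estimated correlation). They were miR-92a-3p (-1.48), miR-20a-5p (-1.54), miR-93-5p (-1.14) and miR-17-5p (-1.12). In miR-30, 2 rose and 3 fell of 9 (2 and 3 adjusted over the list alone; 1 and 3 with the sum of the reference; camera adjusted p = 0.131). In miR-23/27/24, 2 rose and 2 fell of 8 (3 and 3 adjusted over the list alone; 0 and 1 with the sum of the reference), with a median of -0.14 against a camera direction of up (adjusted p = 0.905). The risen members were miR-27a-5p and miR-27b-3p (1.08, adjusted p = 0.0138), and the fallen ones were miR-23a-3p (-1.21) and miR-23b-3p (-1.53). In the miR-10 superfamily, 3 of 10 fell (3 adjusted over the list alone; adjusted p = 0.790 with an estimated correlation). Those were miR-10a-3p (-3.25, on 3, 2 and 3 reads in the belt deletion libraries), miR-99b-3p (-1.87) and miR-99b-5p (-1.79). In let-7 1 of 10 fell, let-7g-5p (1 adjusted over the list alone; camera adjusted p = 0.297).

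Falls were also called for 1 of 2 of miR-29 (miR-29a-3p, -1.92), 1 of 3 of miR-181 (miR-181b-5p, from 70.4 to 3.41; -4.38, adjusted p = 3.17e-10) and 1 of 1 of miR-34 (miR-34a-5p, from 19.5 ± 6.13 to 1.72), with the same counts adjusted over the list alone. For miR-221 with miR-222 it was 1 of 4 (miR-221-3p, -1.89; 2 adjusted over the list alone) and for miR-148 with miR-152 1 of 3, miR-148b-3p (-1.57; 1 fall and 1 rise adjusted over the list alone; 1 rise also under TMM), with a median of 0.54 against a mean of -0.06. edgeR called 0 of 15 DROSHA-independent miRNAs (3 at an unadjusted p under 0.05, 1 by DESeq2; 2 higher under TMM), 0 of 7 of the intestinal list (1 and 0), 0 of 6 of the snoRNA- or tRNA-derived list (0 and 0), 0 of 5 of miR-200 (0 and 0) and 0 of 3 of miR-183 (0 and 0), with 0 adjusted over the list alone. It also called 0 of 2 of miR-15/16 (1 and 0; 1 fall adjusted over the list alone), 0 of 1 of miR-130 with miR-301 (0 and 0), 0 of 2 of the cluster of miR-424 and miR-503 (0 and 0) and 0 of 4 markers of other cell types (1 and 0; 1 higher under TMM), where the paired values are the counts at an unadjusted p under 0.05 and by DESeq2. The median of miR-200 was -0.04 against a camera direction of up (adjusted p = 0.953). The sum of the reference moved the median miRNA by -0.14. For the 29 miRNAs that rose with wild type and were lower with the belt deletion, independent calls would share 12.3 and simulated unchanged groups 0, with the wild type libraries in both contrasts. The simulated value, from groups with hardly any calls, does not measure what these libraries add.

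**Figure D3:**
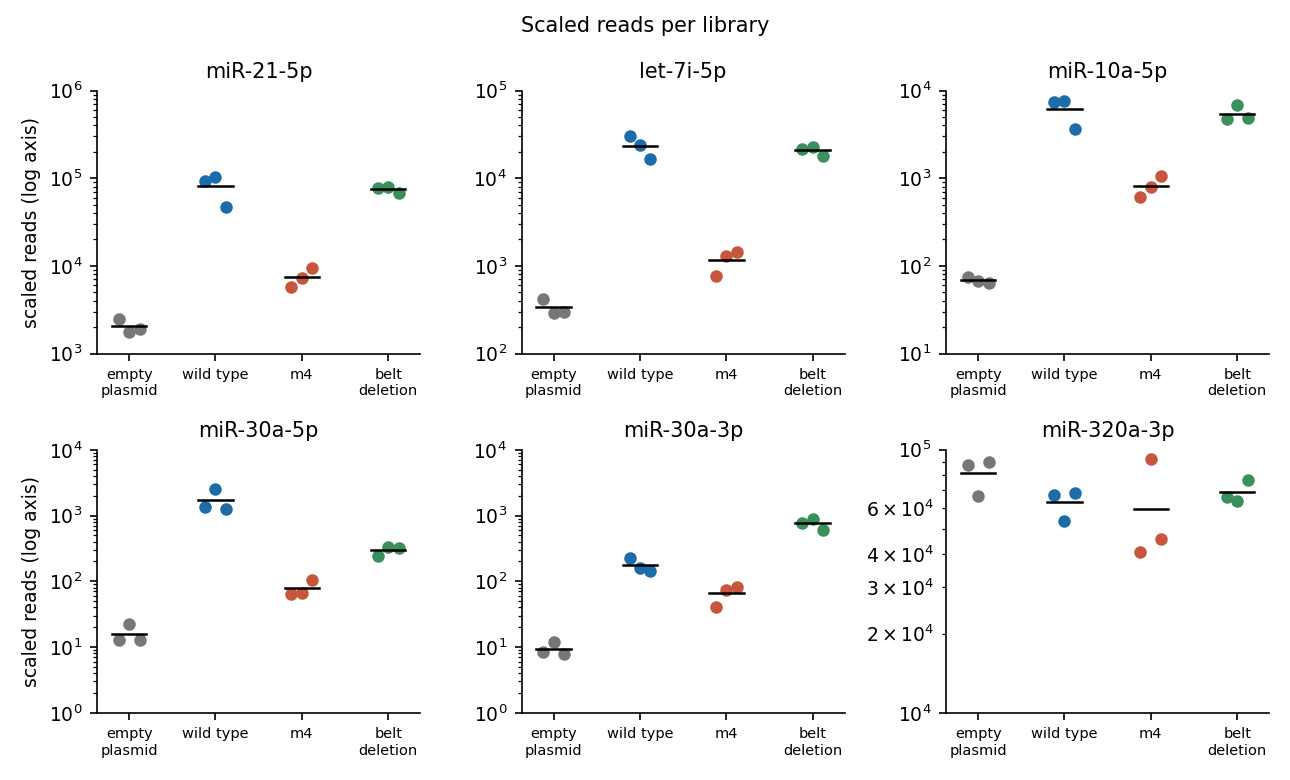
Scaled reads (log y axis) of miR-21-5p, let-7i-5p, miR-10a-5p, miR-30a-5p, miR-30a-3p and miR-320a-3p in each library (points), with the group mean (line). miR-21-5p averages 2052 with the empty plasmid, 80950 with wild type, 7446 with m4 and 74877 with the belt deletion, while miR-30a-3p is higher with the belt deletion (759) than with wild type (175); miR-320a-3p, not called here, was called lower with wild type than with the empty plasmid under TMM, DESeq2 and total-count scaling and higher with m4 than with wild type under total-count scaling.

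The arm shares of 5 of 47 hairpins changed between the belt deletion and wild type. The 3p share of mir-30a was 71.3% ± 5.43 against 10.1% ± 4.21 (SD, n = 3; log2 change of the 5p to 3p ratio -4.57, adjusted p = 9.55e-17), and that of mir-30e was 88.1% ± 1.95 against 39.5% ± 9.53 (-3.52, adjusted p = 8.21e-10). That of mir-10a was 0.0487% ± 0.0102 against 0.442% ± 0.163 (3.06, adjusted p = 0.000213), from only 3, 2 and 3 reads of the 3p arm against 27, 12 and 20. That of mir-216a was 95.7% ± 3.95 against 79.6% ± 14.7 (adjusted p = 0.00238), but not called without wild type 3 (0.251) or belt deletion 1 (0.0573). That of mir-27a was 32.1% ± 1.23 against 57.2% ± 8.57 (adjusted p = 0.0116), but not called without wild type 1 (0.0729), wild type 3 (0.125), belt deletion 1 (0.0657) or belt deletion 3 (0.0517), or by limma (0.0795). With at least 100 reads per library, 1 of 16 hairpins was called, mir-27a. The hairpins mir-30a, mir-30e, mir-10a and mir-216a were not among the 16, so their calls were not tested at that depth.

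**Figure D4:**
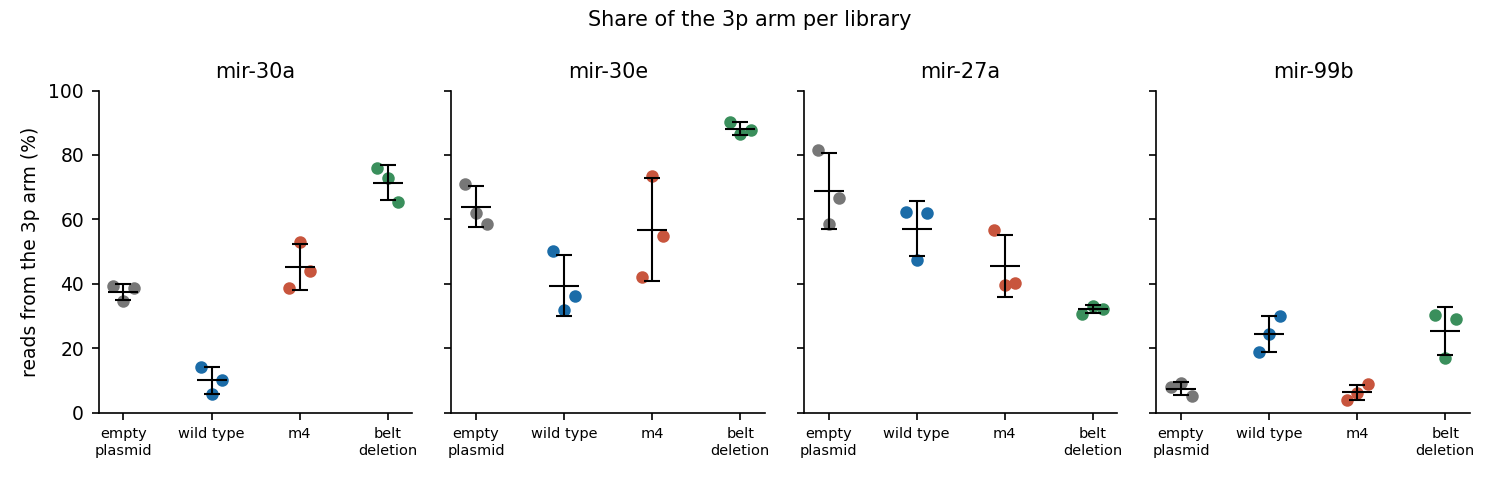
Share of 3p reads in percent of all reads of the hairpins mir-30a, mir-30e, mir-27a and mir-99b (y axis) per library (points), with mean and SD per group (bars). With the belt deletion mir-30a reaches 71.3% and mir-30e 88.1%, against 10.1% and 39.5% with wild type, while mir-27a is at 32.1% against 57.2%.

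The belt deletion against m4 compares the mutants directly. let-7i-5p was 17.7-fold higher with the belt deletion (4.15, SE 0.37, adjusted p = 1.99e-15), miR-30e-3p 15.1-fold (3.92, SE 0.40, adjusted p = 3.49e-13) and miR-769-5p 14.5-fold (3.85, SE 0.42, adjusted p = 2.66e-12). miR-3182 was lower, 130 ± 83.5 against 408 ± 134 (-1.65, SE 0.37, adjusted p = 0.000244; -2.29 without belt deletion replicate 2, -1.32 without replicate 3). In all, 80 miRNAs were higher and 4 lower. The other 3, chosen for mention after their values were seen, were miR-4521 (-1.33), miR-4645-3p (-1.40) and miR-5010-3p (-1.12).

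Higher with the belt deletion were 7 of 10 of let-7 (7 adjusted over the list alone; 2, with 1 lower, under total counts), 6 of 9 of miR-30 (7 adjusted over the list alone; 3, with 1 lower, under total counts), and 5 of 8 of miR-23/27/24 (6 adjusted over the list alone; 4, with 1 lower, under total counts). They also included 4 of 7 of the intestinal list (4 adjusted over the list alone; 3 under total counts). The camera calls of these 4 lists were lost (adjusted p = 0.284 with an estimated correlation). In the miR-10 superfamily it was 5 of 10 (5 adjusted over the list alone; 4, with 2 lower, under total counts; camera adjusted p = 0.166) and in miR-17-92 2 of 7 (2 adjusted over the list alone; 1, with 2 lower, under total counts; camera adjusted p = 0.649). All members of miR-183 (3, but 2 under total counts), miR-221 with miR-222 (4, but 2 under total counts) and miR-148 with miR-152 (3, but 1 under total counts) were higher, with the same counts adjusted over the list alone, as was 1 of 2 of the cluster of miR-424 and miR-503 (2 adjusted over the list alone). Of the other cell type markers 1 of 4 was higher, miR-126-3p (1.43; 1 adjusted over the list alone), but 3 were lower under total counts. No member was called by edgeR in miR-200 (0 of 5, median -0.38; camera adjusted p = 0.101; 4 lower under total counts), the snoRNA- or tRNA-derived list (0 of 6, median 0.12 and mean -0.02; camera adjusted p = 0.175; 2 lower under total counts), miR-29 (0 of 2, median -0.41), miR-181 (0 of 3) and miR-15/16 (0 of 2), each with 1 lower under total counts, or in miR-34 (0 of 1) and miR-130 with miR-301 (0 of 1). In all of these 7 lists 0 were called at an unadjusted p under 0.05, by DESeq2 or adjusted over the list alone. edgeR called 0 of 15 DROSHA-independent miRNAs (2 at an unadjusted p under 0.05, 0 by DESeq2, 0 adjusted over the list alone), and 9 of these were lower under total counts. Their median of 0.03 and mean of -0.07 differ in sign.

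The split of 80 and 4 became 53 and 5 with the sum of the reference, and 47 higher and 121 lower under total counts, where the median miRNA moved by -1.002, against -0.11 under TMM, -0.20 under DESeq2 size factors and -0.33 with the sum of the reference. Calls against the empty plasmid were shared by 111 risen miRNAs in both mutants (54.5 with independent calls, 0.04 in simulated unchanged groups), and 28 miRNAs were lower than wild type in both (9.92 and 0). However, each pair of contrasts shares a control group of 3 libraries, and part of the excess may come from it. The simulated values, from groups with hardly any calls, cannot show how much.

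Arm shares of 6 of 47 hairpins differed between the mutants. The 3p share of mir-30e was 88.1% ± 1.95 with the belt deletion and 56.9% ± 15.8 with m4 (log2 change of the 5p to 3p ratio -2.45, adjusted p = 0.00127), called with each library left out. For the others a left-out library ended the call. The 3p share of mir-99b was 25.4% ± 7.34 against 6.32% ± 2.38 (adjusted p = 0.00953; without belt deletion 1 0.0615, without belt deletion 3 0.0642). That of mir-30a was 71.3% ± 5.43 against 45.3% ± 7.15 (adjusted p = 0.0170; without belt deletion 1 0.188, m4 1 0.0634, m4 3 0.0630; limma 0.0524). That of mir-216a was 95.7% ± 3.95 against 85.6% ± 8.08 (adjusted p = 0.0157; without belt deletion 1 0.203, belt deletion 3 0.103, m4 1 0.105; limma 0.0524). That of mir-21 was 0.136% ± 0.00542 against 0.470% ± 0.278 (adjusted p = 0.0376; without belt deletion 1 0.188, 2 0.0911, 3 0.0630, m4 1 0.248, m4 3 0.166; limma 0.0524). That of mir-10401 was 89.7% ± 5.83 against 98.5% ± 2.62 (adjusted p = 0.0468; without belt deletion 1 0.228, belt deletion 3 0.109, m4 1 0.296, m4 3 0.185; limma 0.0633). With at least 100 reads per library, 1 of 16 hairpins was called, mir-21. The hairpins mir-30e, mir-99b, mir-30a, mir-216a and mir-10401 were not among the 16.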

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

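The tests of other splits of the libraries, of the miR-30 reads, of carry-over, of blood cell RNA and of background reads were chosen only after the result was seen, and the test of depth was chosen before. The test of background reads replaced an earlier version that took the SE before subtraction.

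The mutants moved 7 miRNAs in opposite directions from the same wild type libraries, lower with m4 and higher with the belt deletion. The difference between belt deletion and m4 is the sum of both changes in the same fit, so its p follows from this choice and is no separate evidence. On the log2 scale the difference was 3.53 for miR-30a-3p (-1.41 with m4, 2.12 with the belt deletion; adjusted p = 3.03e-13) and 3.92 for miR-30e-3p (-2.72 and 1.19; adjusted p = 3.49e-13). It was 3.85 for miR-769-5p (-2.15 and 1.70; adjusted p = 2.66e-12), 3.46 for miR-28-3p (-2.37 and 1.10; adjusted p = 4.93e-10) and 2.89 for miR-27b-3p (-1.81 and 1.08; adjusted p = 7.72e-11). For miR-3158-3p it was 3.504 (-1.47 and 2.03, adjusted p = 1.01e-07) and for miR-548o-3p 5.67 (-3.05 and 2.62, adjusted p = 1.05e-11). These 2 were scarce, so their falls with m4 lie near the floor. miR-3158-3p stood at 12.2 ± 5.04 scaled reads with wild type, 3.85 ± 4.19 with m4 and 48.6 ± 8.69 with the belt deletion. miR-548o-3p stood at 10.2 ± 4.40, 1.21 ± 1.29 and 61.5 ± 20.8.

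Over 6 scalings only miR-769-5p and the scarce miR-548o-3p kept both calls. With the sum of the reference the rise with the belt deletion was not called for miR-28-3p, miR-30e-3p and miR-27b-3p, with ranges of adjusted p over the scalings of 0.00831 to 0.353, 0.00273 to 0.205 and 0.000550 to 0.295. Under total counts the fall with m4 was not called for miR-30a-3p, miR-27b-3p and miR-3158-3p, with ranges of 6.31e-05 to 0.286, 8.09e-07 to 0.0548 and 0.0399 to 0.407, and that of miR-3158-3p also not under TMM, DESeq2 size factors and the sum of the reference.

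With the belt deletion the 3p share of mir-30a and mir-30e was higher than with wild type. Reads passed between miR-30 paralogs within an arm would leave the family's ratio of 5p to 3p reads in place, but its log2 value was -0.70 ± 0.45 with the belt deletion and 3.16 ± 0.47 with wild type (SD, n = 3), a difference of -3.85 (exact permutation p = 0.1, the smallest possible), which argues against paralogs as the whole cause. A loss of 5p reads in the counting alone would leave the 3p arm unchanged, but miR-30a-3p was higher under every scaling, by at least 1.98. This argues against such a loss as the whole cause for mir-30a. For mir-30e a loss of 5p reads in the counting cannot be told apart from a change of the cells, because the lowest value of miR-30e-3p over the scalings, 1.04, missed the threshold (adjusted p = 0.205; range over the alternatives 0.000911 to 0.205). The family ratio also lay below wild type with the empty plasmid (1.05 ± 0.24) and with m4 (1.44 ± 0.26). A lower ratio than with wild type was therefore not particular to the belt deletion, though it was lowest there. The 3p share of mir-30e was 71.0%, 62.1% and 58.6% in empty replicates 1 to 3, on few reads and without a call against wild type. An effect of the missing belt on which arm is kept may account for part of the shift of both hairpins, and stays an untested hypothesis.

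The empty libraries held reads of canonical miRNAs. Carry-over of reads from libraries with DROSHA would give each miRNA the same share, but over 36 abundant miRNAs the empty level ranged from 1.64% of the mean of the other 3 groups to 63.1% for miR-4521 and 21.5% for the next (median 5.09%). The SD of the log2 share, 1.10, was 2.91 times the median SE of 0.380 (2.52 times without miR-4521, and 2.21 to 3.93 times against the wild type, m4 or belt deletion mean alone), which argues against carry-over as the whole source. RNA of blood cells would bring miRNAs of blood cells such as miR-142, miR-223 and miR-451a, but these had 3 reads against 507 of let-7a-5p, or 0.592%, which argues against it. RNA with the liver and smooth muscle markers miR-122-5p and miR-143-3p, at 78.8 and 133 scaled reads beside 119 of let-7a-5p, was weighed as a source and stays open, and maturation without DROSHA and DROSHA left in some cells were not tested and could be sources.

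The m4 mutant lowered some miRNAs far more than others. Among the 132 miRNAs that rose with wild type, the SD of the m4 against wild type change was 2.83 times the median SE. With all libraries thinned to 101886 reads it was 2.59 times, with 9 rises and 91 falls called, which argues against depth as the whole cause. After the empty level was subtracted from both groups the log2 ratios of gains spread 1.90 times as far as their own SE after subtraction (2.63 times for the 22 miRNAs with an empty level of at most 10% of the m4 level), which argues against background reads as the whole cause. A different need of each hairpin for what m4 alters may remain, as a hypothesis. The amount of DROSHA in the cells was not measured, so this cannot be told apart from a lower level of the m4 protein.

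For other splits of the 6 libraries of each contrast into 3 and 3, only 10 splits exist, too few for a share under 0.05, and 1 split of 10, the real one, gave as many calls in each case. The real count and the highest of the other splits were 134 and 0 for wild type against empty, 130 and 0 for m4 against empty, 134 and 0 for belt deletion against empty, 117 and 0 for m4 against wild type, 39 and 0 for belt deletion against wild type, and 84 and 0 for belt deletion against m4. For arm ratios they were 8 and 0 for wild type against empty, 3 and 1 for m4 against wild type, 5 and 1 for belt deletion against wild type, and 6 and 0 for belt deletion against m4.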

How the results depend on the processing

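The tests with the earlier tolerance for equal reads, with hairpin copies summed, with only hairpins whose reads stand under 1 hairpin and with a block in 6 libraries were chosen only after the result was seen. Of the results for whole comparisons, 208 kept their direction and side of the threshold, 20 lost the threshold or left a range of 1.5 times downward and 5 did so upward. For single miRNAs these counts were 1383, 15 and 52, and 2 reversed. They were 136, 59 and 0 for single hairpins, and among camera tests of lists 34 lost the threshold and none gained it. Under TMM 218 miRNAs were called for wild type against empty, and under total counts 193 for m4 against wild type and 168 for belt deletion against m4. These scalings moved the median miRNA of the 3 contrasts by -0.86, 1.05 and -1.002. Under total counts miR-320a-3p (0.82) and miR-320b (0.84) turned from lower to higher with m4 than with wild type. This scaling compares shares of all reads. The miR-320 family held 32.9%, 27.9% and 47.0% of the reads in wild type replicates 1 to 3. In m4 replicates 1 to 3 it held 62.2%, 74.4% and 55.3%. With a mean of at least 100 reads per library fewer miRNAs were tested, and 43, 43, 41, 42, 16 and 35 were called for wild type, m4 and belt deletion against empty, m4 and belt deletion against wild type, and belt deletion against m4. With at least 100 reads per hairpin, again fewer tested, 1, 0, 1 and 1 arm ratios were called for wild type against empty, m4 and belt deletion against wild type, and belt deletion against m4. With only hairpins whose reads stand under 1 hairpin 3 arm ratios were called for wild type against empty; part of the loss comes from the 3 hairpins left out. limma called 13 arm ratios for wild type against empty, and 13 with a replicate block; the cause was not tested.

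Leaving out 1 library gave 3 (without empty 3) to 7 arm ratios for wild type against empty, 1 (without wild type 3) to 3 for m4 against wild type, 3 (without wild type 3) to 5 for belt deletion against wild type and 1 (without belt deletion 1) to 6 for belt deletion against m4. In the same 4 contrasts and in m4 and belt deletion against empty, the called miRNAs stayed between 139 and 150, 98 and 129, 29 and 42, 75 and 82, 112 and 140, and 128 and 141. Replicate numbers were tested as a pairing with 155 miRNAs: 6 of 18 pairs of libraries with 1 number correlated above 0.1 (-0.56 to 0.42), of which 3 were the 3 pairs of wild type and m4, and 1 of 12 libraries was closest to its own number. With a replicate block 134, 130, 133, 112, 38 and 83 miRNAs were called for wild type, m4 and belt deletion against empty, m4 and belt deletion against wild type, and belt deletion against m4. For m4 against wild type, where every pair was above 0.1, the block took the count from 117 to 112, or to 95 in a fit of these 6 libraries (108 without the block), and it changed no call of the naming rule or of camera. The arm call of mir-16-2 there was lost by limma with or without it. For belt deletion against wild type, where the numbers pair nothing, miR-28-3p was not called with the block (adjusted p = 0.0516; range over the alternatives 0.00478 to 0.353). Depth limits the weakest miRNAs, as m4 replicate 1 has 101886 reads.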

Other observations

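The tests of 3p against 5p arms and of the difference in arm agreement, and the miRNAs named in the next paragraph, were chosen only after the result was seen, and the tests of GC content, folding energy and arm agreement before.

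Of the 310 miRNAs, 146 were called in none of the 6 contrasts. Outside the DROSHA-independent list, 5 of them had at least 500 mean scaled reads in the empty libraries. They were miR-3615 (7760 ± 1876, SD, n = 3), miR-7706 (6775 ± 1410), miR-7974 (3193 ± 1745), miR-10399-3p (740 ± 55.1) and miR-1292-5p (543 ± 22.9). With wild type they stood at 5435, 4549, 3907, 628 and 539 scaled reads, and miR-3615 and miR-7706 were called lower there under TMM, DESeq2 and total-count scaling. The miRNAs higher with m4 than with wild type were miR-3182, miR-10525-3p, miR-1257, miR-3913-3p, miR-3917, miR-4645-3p, miR-4743-5p, miR-6505-5p, miR-6515-5p, miR-6761-5p and miR-6842-3p. Besides those named above, miR-3158-3p, miR-548o-3p and miR-625-3p were higher with the belt deletion than with wild type. The reads of miR-3158-3p and miR-625-3p stand under their 5p names as well. miR-181b-5p was 70.4 with wild type and 3.41 with the belt deletion, while miR-181a-5p was 135 and 91.4 (not called). Reads of miR-1268a were uneven within groups, with 829 in m4 replicate 2, 362 in belt deletion replicate 1, 26 in wild type replicate 2, 1 in empty replicate 3 and 0 in the others. miR-216a-3p had 729, 93 and 567 reads in the belt deletion libraries.

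Loss of a miRNA may go with the composition or stability of its hairpin. Across the 112 hairpins of the risen miRNAs, which are not independent replicates, the belt deletion against wild type change went with GC content (Spearman's rho 0.232, Pearson's r 0.191, permutation p = 0.0134, adjusted p = 0.0268 over 4 relations). It went with folding energy per base in the opposite direction (rho -0.260, r -0.299, permutation p = 0.00605, adjusted p = 0.0242), so that more stable hairpins were kept more. Over the 102 hairpins without a called arm ratio rho was 0.220 and -0.250. For m4 against wild type rho was 0.070 with GC content (interval -0.117 to 0.252, adjusted p = 0.461) and -0.0951 with folding energy (interval -0.276 to 0.0920, adjusted p = 0.424), intervals that lay within the bound set before. The difference between the mutants was not tested.

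If a mutant acts on the whole hairpin, its arms should change alike. Across 37 hairpins with both arms tested, rho between the arms was 0.760 for wild type against empty and 0.803 for m4 against wild type (permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 1.5e-05 over 3 relations). It was 0.199 for belt deletion against wild type (permutation p = 0.237), which leaves agreement open there. In the 33 hairpins whose reads stand under 1 hairpin in both arms the 3 values of rho were 0.759, 0.794 and 0.192. The difference between the mutants was 0.604 (permutation p = 0.00173). That the arms change less alike with the belt deletion is a hypothesis found and tested on the same data. The 37 hairpins were not limited to those of risen miRNAs and include DROSHA-independent ones such as mir-877 and mir-1226. A difference between kinds of hairpin could raise rho where canonical miRNAs change strongly, so the test cannot decide this. The mean change of 52 3p arms minus that of 80 5p arms was 0.0989 for m4 (permutation, adjusted p = 0.628) and 0.397 for the belt deletion (permutation p = 0.0402, adjusted p = 0.0803). The latter lay below the bound of 0.5 times the SD of the changes, 0.547, but not by more than its spread (SE 0.198). This last condition was added after the result was seen, so a general shift toward 3p arms stays open for the belt deletion. miR-3158-3p and miR-625-3p, higher with the belt deletion by 2.03 and 1.75, count as 3p arms here. Their reads stand under the 5p names as well, so their arm is uncertain.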
